A study of Homo sapiens with 12 samples.

How the data were processed

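Poly-A RNA of human U2OS osteosarcoma cells was sequenced in 12 libraries, 3 labelled biological replicates in each of 4 groups, a control, 30 min in 50 µM CCCP, and 1 h and 6 h after a change to fresh medium that followed the same exposure. Per the labels' protocols, RNA was taken up in TRIzol, messenger RNA was captured on poly-T beads and cDNA was primed with random hexamers. The labels state no strand setting, so reads of a gene and of a transcript antisense to it cannot be told apart in these counts, and the counts of near-identical copies, such as HSPA1A and HSPA1B or the 7SL RNA genes, are uncertain.

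Per the submitters' processing notes, the steps before deposit used fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with the human genome build GRCh38 (hg38), and the notes give no annotation release and no settings. The authors deposited whole-number counts per gene and library, not normalized, per the file headers. FPKM values and a gene length were deposited beside them, per the file headers, which do not say how the FPKM were scaled. Counts divided by that length and by the library total gave 0.982 to 1.05 times the deposited FPKM (median ratio per library). The ratio was 1.03 to 1.05 in controls and 0.982 to 0.995 at 6 h, so the deposited values were not scaled by these totals alone. The authors' log2 fold changes of their own group comparisons were deposited too, per the file headers, with the first named group over the second. Each has an unadjusted p-value and an adjusted p-value from the authors, and the adjusted p-value was 1 for many genes with low counts. The counts were used for every test here, and the other deposited values only where the text names them as deposited. A deposited comparison of 6 h with the end of the exposure was left out, since it joins the 2 steps of recovery tested here.

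The table held 61839 genes, of which 19076 had no counts in any library and 306 had no gene name. The unnamed ones held 0.250 to 0.335% of each library's counts, 123 gene symbols stood for more than 1 gene identifier, and 46 pseudoautosomal copies on chromosome Y were kept apart by identifier. Total counts per library ran from 13512353 to 16361338, and the 10 genes with the most counts took 5.34 to 6.16% of them. Replicates differed by more than counting error, with a chi-square per degree of freedom of 1.71 to 5.96 between pairs of replicates, over genes with at least 20 counts in the pair. Reads carry no molecular identifiers, so depth sets the counting error only, and the test takes its error from the spread between replicates.

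Groups, tests, lists, alternatives and the rule for named genes were set before the data were examined, except where an addition is named. Genes were kept with the edgeR function filterByExpr by group (minimum count 10, minimum total count 15), which left 18790. Counts were scaled with TMM factors (0.980 to 1.04) and tested with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion, in R 4.3.3, in 1 model of the 4 groups over all 12 libraries with no other term. The 5 comparisons set each treated group against control, 1 h against the end of the exposure and 6 h against 1 h, and a sixth test asked for any difference among the 4 groups. All tests were two-sided, p values were adjusted by Benjamini-Hochberg within a comparison, and an adjusted p under 0.05 counted as a call. Every adjusted p of a gene in the text is edgeR's unless another tool is named, n = 3 libraries per group throughout, and log2 fold changes stand with their standard error from that model. CPM values use TMM-scaled library sizes, and log CPM values a prior count of 2.

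Gene lists numbered 27 with 9 to 71 members, 680 of which matched a symbol in the table, and 26 lists with at least 5 tested members were tested. Lists held immediate early genes, the integrated stress response, mitochondrial chaperones and proteases, the unfolded protein response of the endoplasmic reticulum, heat shock, mitophagy, mitochondrial dynamics, lysosome and autophagy, genes of mitochondrial DNA, nuclear oxidative phosphorylation, mitochondrial biogenesis, glycolysis, hypoxia, NRF2, NF-kB, interferon, p53, cholesterol synthesis, MAP kinase feedback, YAP and TEAD, MondoA and FOXO, metallothioneins, S phase entry, mitosis, ribosomal proteins, RNAs without a poly-A tail and markers of other cell types. They were written from general knowledge and hold some genes in common. The camera test of limma 3.58.1 with a preset correlation between genes of 0.01 compared each list with all other tested genes, adjusted over the 130 tests of 26 lists and 5 comparisons, and camera with a correlation estimated for each list stands beside it. Counts of members "adjusted over the list alone" use edgeR p values adjusted within the list and comparison.

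Named genes followed 3 rules. For each comparison, the first took the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 2, a gene symbol, and values of the 2 groups that did not overlap (chance gives 10% of genes such a gap for 3 libraries against 3). For each list and comparison, the second took up to 4 called members with the largest changes. Under the third rule, PINK1, ATF4, ATF3, DDIT3, FOS, EGR1, GDF15, PPARGC1A, TXNIP, HMOX1, HSPA1A, TFAM, SQSTM1, TRIB3, CHAC1, HSPD1, MT-ND1 and MT-CO1 were named whether or not they passed. The text prints fewer of the first 2 kinds, from the top, and says where a gene was chosen after its values were seen.

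Alternatives changed 1 choice at a time, except that DESeq2 changed the test, the scaling and the filtering together, and fits on fewer libraries chose the tested genes anew. They were DESeq2 1.42.0 with its own size factors and filtering, limma-voom, RLE size factors, scaling to library size only, a filter of at least 1 CPM in at least 3 libraries, no filter beyond 1 count, the replicate number as a term, the 2 groups fitted alone, an adjusted p under 0.01, the estimated correlation for lists, and each library left out in turn. A further 2 were added after the data were seen, a correction of each library for GC content, a spline with 5 degrees of freedom on the deviations of genes with a mean log2 CPM above 2, for the 18123 tested genes (96.5%) with a GC value from their longest GENCODE transcript, and a fit without the 3 libraries that deviated together.

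The methods were tested on simulated counts with the real means, library sizes and spread, with each gene drawn independently of the others. In a simulated comparison of 1 h with control over 18373 genes, 15 of 50 genes changed 1.25-fold were called, 31 of 50 at 1.5-fold, 32 of 50 at 2-fold and 48 of 50 at 4-fold, while 16 of 152 calls (10.5%) were false. In the same draw, groups simulated as unchanged against those controls gave 0 calls at 30 min and 4 at 6 h. A list of 30 genes raised 1.25-fold had an adjusted p of 1.14e-16 (3.91e-04 with an estimated correlation), and 0 of 125 tests of unchanged lists passed. Since the simulated genes were independent, this does not test the preset correlation on lists whose members move together. In the data the estimated correlation of the ribosomal protein list was 0.448 at 30 min. With a GC slope simulated in the 30 min comparison over 18384 genes, 3101 genes were called without the correction and 2 with it. Calls shared between comparisons with the same controls were set beside the product of the 2 lists' sizes over the genes tested. They were also set beside simulated unchanged groups against shared simulated controls, with every gene drawn independently from the control means.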

Results

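RNA from human U2OS cells, an osteosarcoma line, was sequenced in 12 poly-A selected libraries that formed 4 groups of 3 biological replicates per the labels. The groups were a control, cells collected at the end of 30 min in 50 µM CCCP (carbonyl cyanide m-chlorophenylhydrazone, a protonophore that uncouples mitochondrial respiration from ATP synthesis), and cells collected 1 h and 6 h after the CCCP was replaced with fresh medium. The sample titles call the controls untreated and the treatment protocol names DMSO, so the labels leave open which of these the controls received. No group was given fresh medium without CCCP, so the 1 h and 6 h comparisons with control hold both the recovery from CCCP and the change of medium. Total counts per library ran from 13512353 to 16361338, and 18790 genes were tested. Replicates differed by a biological coefficient of variation of 5.66% across tested genes. Transcripts of mitochondrial DNA took 4.27 ± 0.180% of counts in controls, 4.27 ± 0.289% at 30 min, 4.05 ± 0.0697% at 1 h and 3.76 ± 0.116% at 6 h (mean ± SD, n = 3 libraries). The first principal component (31.4% of the variance) set the 6 h libraries apart from all others, and the second (14.9%) had the 1 h libraries at its lower end. On the second, CCCP replicate 1 (12.13) lay within the range of the controls (12.03 to 18.12), and CCCP replicates 2 and 3 lay at -0.18 and 0.29. Control replicate 1, CCCP replicate 1 and 6 h replicate 3 deviated from their groups together, with a Spearman rho across genes between deviation and GC content of -0.53, -0.63 and -0.62, and genes are not independent replicates. The log2 fold changes against control also followed GC content, with a rho of 0.38 at 30 min, 0.36 at 1 h and 0.05 at 6 h.

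**Figure D1:**
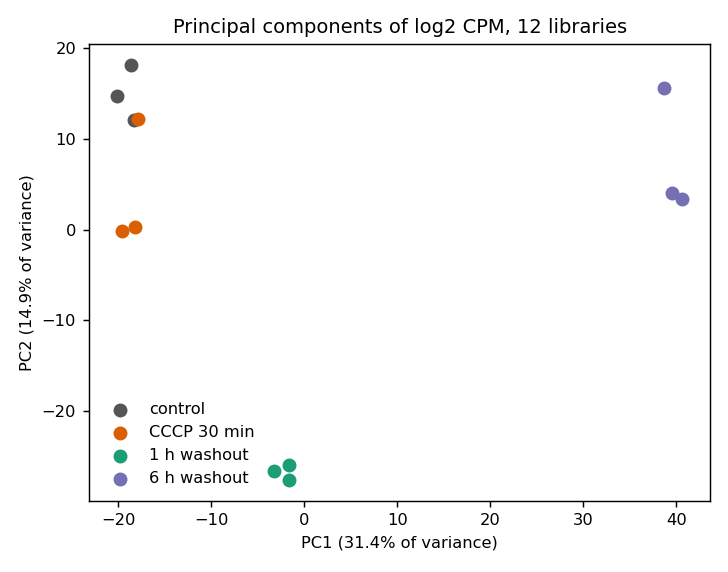
Principal components of log2 CPM of the 12 libraries, with the first component on the horizontal axis and the second on the vertical axis, 1 point per library and 1 colour per group. The 6 h libraries lie between 38.7 and 40.6 on the first component, and every other library lies below 0 on it.

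The first comparison asked which transcripts differed at the end of the 30 min in CCCP, before the washout. Immediate early genes, the transcription factors and feedback regulators that cells induce within minutes of a stimulus, were higher. FOS (ENSG00000170345_10, chromosome 14, 75278826 to 75282230, GRCh38), a subunit of the AP-1 transcription factor, rose 5.78-fold, from 7.98 ± 1.18 CPM (library-scaled counts) in controls to 46.5 ± 5.96 CPM (mean ± SD, n = 3 libraries per group), with an edgeR adjusted p = 2.94e-17. EGR1 (ENSG00000120738_8, chromosome 5, 138465479 to 138469303), a zinc finger transcription factor, rose 3.04-fold from 84.7 ± 8.28 to 257 ± 23.2 CPM (edgeR adjusted p = 1.55e-08). The AP-1 subunits FOSB and JUNB rose by 1.48 ± 0.23 and 0.98 ± 0.10 on the log2 scale (± SE), and ZFP36, which promotes decay of AU-rich mRNA, rose by 1.17 ± 0.14. DUSP1, a phosphatase that inactivates MAP kinases, rose 2.21-fold to 61.4 ± 6.99 CPM, and ATF3, a stress-induced transcription factor, rose 2.01-fold to 28.6 ± 1.61 CPM. CCN1, a secreted matricellular protein and target of YAP, rose 1.66-fold to 424 ± 9.55 CPM. Of 31 tested immediate early genes 16 rose and 0 fell, and 21 rose when adjusted over the list alone (camera adjusted p = 3.09e-104, and adjusted p = 3.17e-04 with an estimated correlation). MIR17HG, the host transcript of the miR-17-92 microRNA cluster, fell by 1.15 on the log2 scale, from 5.24 ± 0.435 to 2.36 ± 0.296 CPM (edgeR adjusted p = 3.61e-04). That adjusted p ran from 1.60e-04 to 0.0132 over the alternatives run on named genes, while DESeq2 gave it none. Limma-voom and the fit without a low-count filter were not run on named genes.

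In all, edgeR called 73 genes at 30 min, 42 higher and 31 lower, of which 7 rose and 3 fell at least 2-fold. The count was 32 without control replicate 1, 33 without control replicate 2, 319 without CCCP replicate 1, 46 without CCCP replicate 2, 27 without CCCP replicate 3 and 253 without the 3 libraries that deviated together. It was 161 without a low-count filter, 144 after a GC correction, 41 with the 2 groups fitted alone and 38 with limma-voom. The share of called genes that were higher, 57.5% here, was 34.8% with scaling to library size only (24 higher, 45 lower), 43.8% after the GC correction (63 and 81) and 70.2% with DESeq2 (59 and 25).

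Other groups moved less at 30 min. Among 20 targets of YAP and TEAD, which respond to cell shape and tension, 4 rose and 0 fell (6 rose when adjusted over the list alone; camera adjusted p = 9.75e-16, and adjusted p = 0.00161 with an estimated correlation). They were led by CCN1 and CCN2, which the immediate early list also holds. Among 17 heat shock genes 2 rose, the paralogs HSPA1A and HSPA1B, which share much of their sequence (4 adjusted over the list alone). The list had a camera adjusted p of 9.08e-08, and adjusted p = 0.0117 with an estimated correlation. HSPA1A changed by 0.33 ± 0.07 (adjusted p = 0.0166), and its adjusted p was 0.141 and 0.0815 without control replicate 1 or 2 and 0.0754 and 0.137 without CCCP replicate 2 or 3. HSPA1B changed by 0.35 ± 0.08 (adjusted p = 0.0310), and its adjusted p was 0.131, 0.0692 and 0.116 without control replicate 1, 2 or 3 and 0.0595 and 0.256 without CCCP replicate 2 or 3. It was 0.0519 with scaling to library size only and 0.0779 with the 2 groups fitted alone. None of 22 genes of the unfolded protein response of the endoplasmic reticulum passed alone, while the list lay above other genes (median log2 change 0.04, camera adjusted p = 0.00503, and 0.0345 with an estimated correlation). Another 5 lists passed the preset test and not the one with an estimated correlation. Of 71 cytosolic ribosomal protein genes 2 rose (11 adjusted over the list alone; median 0.10, adjusted p = 2.35e-16, and adjusted p = 0.196 with an estimated correlation). The calls of these 2, RPS15 and RPL37A, were lost under 4 and 5 of 14 alternatives. Of 70 nuclear genes of oxidative phosphorylation 2 rose (2 adjusted over the list alone; median 0.08, adjusted p = 6.64e-06, and adjusted p = 0.265 with an estimated correlation). Those 2, NDUFB7 and ATP5F1E, lost their calls under 10 and 8 of 14 alternatives. Of 14 feedback targets of MAP kinase signalling 1 rose, IER3, by 0.67 ± 0.08 (3 adjusted over the list alone). Tested as a list, these genes had an adjusted p of 2.13e-05, and adjusted p = 0.0748 with an estimated correlation. ATF3 was the 1 gene that rose among 40 of the integrated stress response (2 adjusted over the list alone; adjusted p = 2.50e-05, and adjusted p = 0.0534 with an estimated correlation). In the p53 list 2 of 22 targets rose (3 adjusted over the list alone). They were GADD45A and CDKN1A, whose calls were lost under 6 and 9 of 14 alternatives. The list's adjusted p was 0.00298, and adjusted p = 0.0522 with an estimated correlation.

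**Figure D2:**
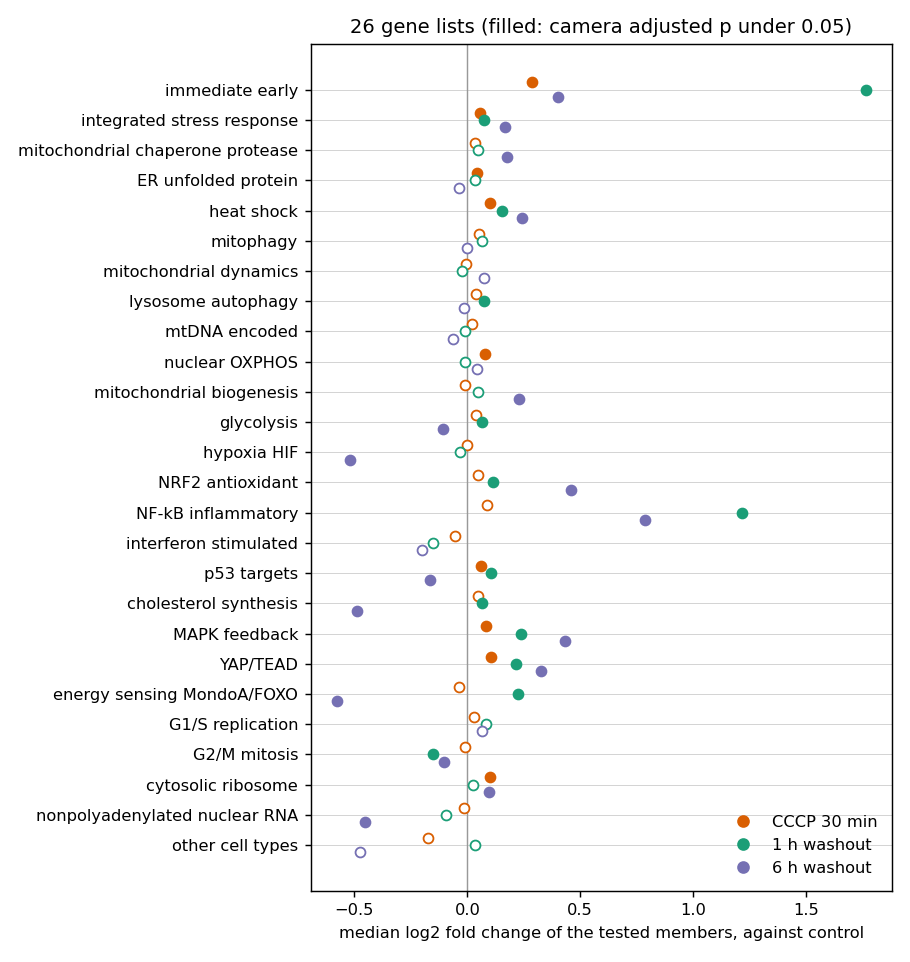
Median log2 fold change against control of the 26 tested gene lists (vertical axis) at 30 min of CCCP and at 1 h and 6 h after washout (horizontal axis, log2 fold change), with filled points where the camera adjusted p passed the threshold. The median of the immediate early list is 0.28, 1.77 and 0.40 at the 3 times, and that of the cholesterol synthesis list 0.05, 0.07 and -0.49.

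The second comparison asked how cells differed from controls 1 h after washout. Immediate early and inflammatory transcripts were high. FOSB rose by 4.45 ± 0.18 on the log2 scale, and EGR1 rose 16.1-fold, from 84.7 ± 8.28 to 1362 ± 52.1 CPM (mean ± SD, n = 3 libraries per group, edgeR adjusted p = 6.43e-15). CXCL8 (ENSG00000169429_11, chromosome 4, 73740541 to 73743716), which encodes the neutrophil chemoattractant interleukin 8, rose 8.82-fold, from 1.27 ± 0.184 to 11.3 ± 0.811 CPM (adjusted p = 9.38e-14). JUNB rose by 3.00 ± 0.09, FOS by 2.86 ± 0.10 and DUSP2, a further MAP kinase phosphatase, by 2.78 ± 0.13. TNFAIP3, the A20 inhibitor of NF-kB, rose 6.20-fold to 56.1 ± 4.79 CPM, and FOSL1 rose by 2.63 ± 0.12. Of the immediate early list, 30 of 31 rose and 0 fell (30 rose adjusted over the list alone; the camera p with the preset correlation was too small to be printed, and the adjusted p was 2.44e-05 with an estimated correlation). Of 17 inflammatory targets of NF-kB, 15 rose and 0 fell (16 rose adjusted over the list alone; adjusted p = 4.52e-49, and 1.09e-04 with an estimated correlation), among them PTGS2, which encodes cyclooxygenase 2, by 2.20 ± 0.14.

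Stress and growth control transcripts rose with them at 1 h. In the integrated stress response list 15 of 40 rose and 0 fell (16 rose adjusted over the list alone). As a set they had a camera adjusted p of 3.63e-15, and adjusted p = 0.00374 with an estimated correlation. Among those that rose were ATF3 by 2.37 ± 0.08, PPP1R15A, which directs dephosphorylation of eIF2 alpha, by 1.80 ± 0.07, GDF15 by 1.37 ± 0.15, DDIT3, which encodes CHOP, by 1.15 ± 0.12, and CHAC1 by 1.08 ± 0.09. ATF4, the transcription factor that drives this response, rose by 0.22 ± 0.05 (adjusted p = 0.00155), and TRIB3 was at 0.22 ± 0.10 (adjusted p = 0.143, and 0.0187 without control replicate 3). Of 20 YAP and TEAD targets 11 rose (11 adjusted over the list alone; adjusted p = 1.74e-41), with CCN2 at 3.34-fold, and of 14 MAP kinase feedback targets 10 rose (11, with 1 fallen, adjusted over the list alone; adjusted p = 2.32e-34), with DUSP5 at 1.77 ± 0.08. Of 22 p53 targets 10 rose (10 adjusted over the list alone; adjusted p = 2.98e-14), among them PLK3 by 1.24 ± 0.10 and GADD45A by 1.12 ± 0.06. Of 17 heat shock genes 9 rose (11 adjusted over the list alone; adjusted p = 8.78e-06), with HSPA1A at 0.35 ± 0.07. Of 15 targets of MondoA and FOXO, which respond to glucose and energy state, 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 5.24e-07), and KLF10 rose by 1.93 ± 0.06 and TXNIP, an inhibitor of thioredoxin and glucose uptake, by 0.71 ± 0.13. Of 21 antioxidant targets of NRF2 6 rose (9 adjusted over the list alone; adjusted p = 2.00e-04), with OSGIN1 at 1.38 ± 0.11 and HMOX1, heme oxygenase 1, at 0.64 ± 0.07.

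With an estimated correlation the adjusted p values at 1 h were 1.15e-04 for the YAP and TEAD list, 6.55e-04 for MAP kinase feedback, 6.72e-04 for p53, 0.0258 for heat shock, 0.00548 for MondoA and FOXO and 0.0254 for NRF2. Of 24 mitotic genes 9 fell and 0 rose (13 fell adjusted over the list alone; camera adjusted p = 6.06e-05, and adjusted p = 0.196 with an estimated correlation). The largest falls were those of the spindle checkpoint kinase TTK at -0.32 ± 0.07 and DLGAP5 at -0.26 ± 0.05. A further 3 lists passed the preset test alone. They were glycolysis with 5 of 22 risen (5 adjusted over the list alone; adjusted p = 0.0159, and adjusted p = 0.427 with an estimated correlation), lysosome and autophagy with 6 of 31 risen (6, 0.0158 and 0.0857 in the same order) and cholesterol synthesis with 4 of 22 risen (5, with 2 fallen, 0.040 and 0.0868). Their preset adjusted p was 0.163 for glycolysis and 0.0514 for lysosome and autophagy after the GC correction, 0.0930 for glycolysis and 0.0637 for cholesterol synthesis without control replicate 3, and for cholesterol synthesis 0.0911 without 1 h replicate 3 and 0.0763 with a filter of at least 1 CPM in 3 libraries. Among the largest falls were RN7SL3, a copy of the 7SL RNA that has no poly-A tail, at -2.29 ± 0.39, and RN7SL1, a near-identical copy, at -2.19 ± 0.54. The adjusted p of RN7SL1 was 0.0378 and ran from 0.0354 to 0.132 with 1 library left out, past the threshold only without control replicate 1, and it was 0.0767 with the replicate number as a term. SOCS3, a feedback inhibitor of cytokine signalling, fell 2.32-fold from 33.8 ± 1.19 to 14.5 ± 0.347 CPM (adjusted p = 2.50e-10), and the transcription factor SOX2 fell 2.25-fold from 15.5 ± 0.113 to 6.88 ± 0.801 CPM (adjusted p = 1.02e-08).

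At 1 h edgeR called 1930 genes against control, 1215 higher and 715 lower, of which 118 rose and 141 fell at least 2-fold. The count was 1190 and 1281 without control replicate 1 or 2, 1134, 1246 and 1252 without 1 h replicate 1, 2 or 3, and 3159 with the 2 groups fitted alone. The share of called genes that were higher, 63.0%, was 35.4% with scaling to library size only (746 higher, 1361 lower) and 75.6% with DESeq2 (1202 and 387), and that scaling moved the median of all tested genes to -0.03, -0.07 and -0.08 at 30 min, 1 h and 6 h.

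The third comparison asked what differed from controls 6 h after washout, the comparison with control that called the most genes. Antioxidant genes driven by NRF2 were high, and genes of cholesterol synthesis and the hypoxia response were low. TXNRD1 (ENSG00000198431_17, chromosome 12, 104215779 to 104350307), thioredoxin reductase 1, rose 3.48-fold, from 171 ± 3.03 to 596 ± 18.1 CPM (mean ± SD, n = 3 libraries per group, edgeR adjusted p = 1.09e-22), OSGIN1 rose by 2.13 ± 0.11, SRXN1, sulfiredoxin, by 1.53 ± 0.17, and SLC7A11, the cystine importer, 2.44-fold to 351 ± 19.8 CPM. Of 21 NRF2 targets 17 rose and 0 fell (17 rose adjusted over the list alone). The list had a camera adjusted p of 2.61e-28, and adjusted p = 1.15e-04 with an estimated correlation. Of 22 cholesterol synthesis genes 21 fell and 0 rose (21 fell adjusted over the list alone). Tested as a list, these genes had an adjusted p of 1.41e-23, and adjusted p = 8.97e-05 with an estimated correlation. INSIG1 (ENSG00000186480_13, chromosome 7, 155297776 to 155310235), the sterol-responsive retention protein of the endoplasmic reticulum, fell 2.50-fold from 47.4 ± 2.14 to 18.9 ± 1.93 CPM (adjusted p = 1.48e-14), and HSD17B7 and STARD4 had log2 changes of -1.09 ± 0.09 and -0.94 ± 0.05. In the list of 23 targets of HIF 18 fell and 1 rose (20 and 1 adjusted over the list alone). The list's adjusted p was 2.39e-15, and adjusted p = 0.00792 with an estimated correlation. STC1 was at -2.00 ± 0.21. PFKFB4, a regulator of fructose bisphosphate, fell 3.73-fold, EGLN3, a HIF prolyl hydroxylase, 2.81-fold, and BNIP3, a mitophagy receptor, 2.27-fold from 62.9 ± 4.86 to 27.7 ± 2.64 CPM.

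Energy sensing and mitochondrial upkeep genes also moved at 6 h. In the MondoA and FOXO list 9 of 15 fell and 4 rose (10 and 4 adjusted over the list alone). As a set they had a camera adjusted p of 1.08e-04, and adjusted p = 0.0166 with an estimated correlation. The ubiquitin ligase FBXO32 was at -1.41 ± 0.10, the cyclin CCNG2 at -1.23 ± 0.07 and SESN3 at -1.22 ± 0.08, while TXNIP rose by 0.63 ± 0.13. Of 17 genes of mitochondrial biogenesis 9 rose and 0 fell (10 rose adjusted over the list alone; adjusted p = 5.54e-05, and 0.00881 with an estimated correlation). TWNK, the mitochondrial DNA helicase, rose by 0.89 ± 0.07, the coactivators PPARGC1B by 0.87 ± 0.11 and PPRC1 by 0.72 ± 0.06, and TFAM, which packages mitochondrial DNA, by 0.31 ± 0.06. Of 15 mitochondrial chaperones and proteases 7 rose (8 adjusted over the list alone; adjusted p = 0.0180, and adjusted p = 0.0694 with an estimated correlation), with GRPEL1 at 0.54 ± 0.09 and HSPD1, the chaperonin HSP60, at 0.33 ± 0.05. Of 40 integrated stress response genes 21 rose and 5 fell (21 and 5 adjusted over the list alone). The list had a camera adjusted p of 1.82e-04, and adjusted p = 0.0748 with an estimated correlation. The members moved apart: SLC7A5, an amino acid transporter, rose by 0.90 ± 0.05 and TRIB3 by 0.53 ± 0.09, while DDIT4, an inhibitor of mTORC1, was at -1.59 ± 0.07 and ATF3 at -0.48 ± 0.10. ATF4 was at 0.17 ± 0.05 (adjusted p = 0.00610, 0.0513 without control replicate 2 and 0.0801 with scaling to library size only). GDF15 was at -0.57 ± 0.19 (adjusted p = 0.0175, and 0.0847, 0.0881, 0.0767 and 0.0550 without control replicate 2 or 3 or 6 h replicate 2 or 3). DDIT3 was at -0.24 ± 0.13 (adjusted p = 0.167) and CHAC1 at -0.05 ± 0.09 (adjusted p = 0.727).

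Part of the 1 h response was still high at 6 h. In the immediate early list 19 of 31 were higher and 4 lower than control (21 and 4 adjusted over the list alone; camera adjusted p = 5.38e-15, and 0.0475 with an estimated correlation). FOSL1 was at 1.74 ± 0.12, MYC at 1.38 ± 0.07 and EGR1 at 0.92 ± 0.08, while FOS was at 0.22 ± 0.12 (adjusted p = 0.185, and 0.0461 without control replicate 1). Of 17 NF-kB targets 13 were higher (13 adjusted over the list alone; adjusted p = 1.31e-06, and 0.0166 with an estimated correlation). Of 14 MAP kinase feedback targets 10 were higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 7.52e-07, and 0.0481 with an estimated correlation). Of 20 YAP and TEAD targets 12 were higher and 5 lower (13 and 6 adjusted over the list alone; adjusted p = 1.59e-06, and 0.020 with an estimated correlation). CCN2 stayed 3.28-fold above control. Of 17 heat shock genes 11 rose (11 adjusted over the list alone; adjusted p = 2.36e-04, and adjusted p = 0.0538 with an estimated correlation), with HSPA8 at 0.60 ± 0.04 and HSPA1A at 0.27 ± 0.07. Among 22 p53 targets 11 fell and 3 rose (11 and 3 adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.0857 with an estimated correlation), with TP53INP1 at -1.09 ± 0.08. In glycolysis 9 of 22 genes fell and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 0.00295, and adjusted p = 0.340 with an estimated correlation). The glucose transporter SLC2A1 was at -0.63 ± 0.05. Mitotic genes fell in 11 and rose in 2 of 24 cases (11 and 2 adjusted over the list alone; adjusted p = 0.0407, and adjusted p = 0.490 with an estimated correlation). Ribosomal protein genes rose in 13 of 71 cases (0 adjusted over the list alone). Tested as a list, these genes had an adjusted p of 0.0168, and adjusted p = 0.732 with an estimated correlation. The preset adjusted p of the mitotic list was 0.0914, 0.0919 and 0.0766 without control replicate 1 or 6 h replicate 1 or 2. That of the ribosomal list was 0.0695 and 0.157 without 6 h replicate 2 or 3, 0.0749 after the GC correction and 0.130 without the 3 libraries that deviated together. Among 13 nuclear RNAs and histone genes without a poly-A tail, whose counts can reflect library selection or expression, 7 fell and 0 rose (7 fell adjusted over the list alone). The list's adjusted p was 8.78e-04, and adjusted p = 0.0857 with an estimated correlation.

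**Figure D3:**
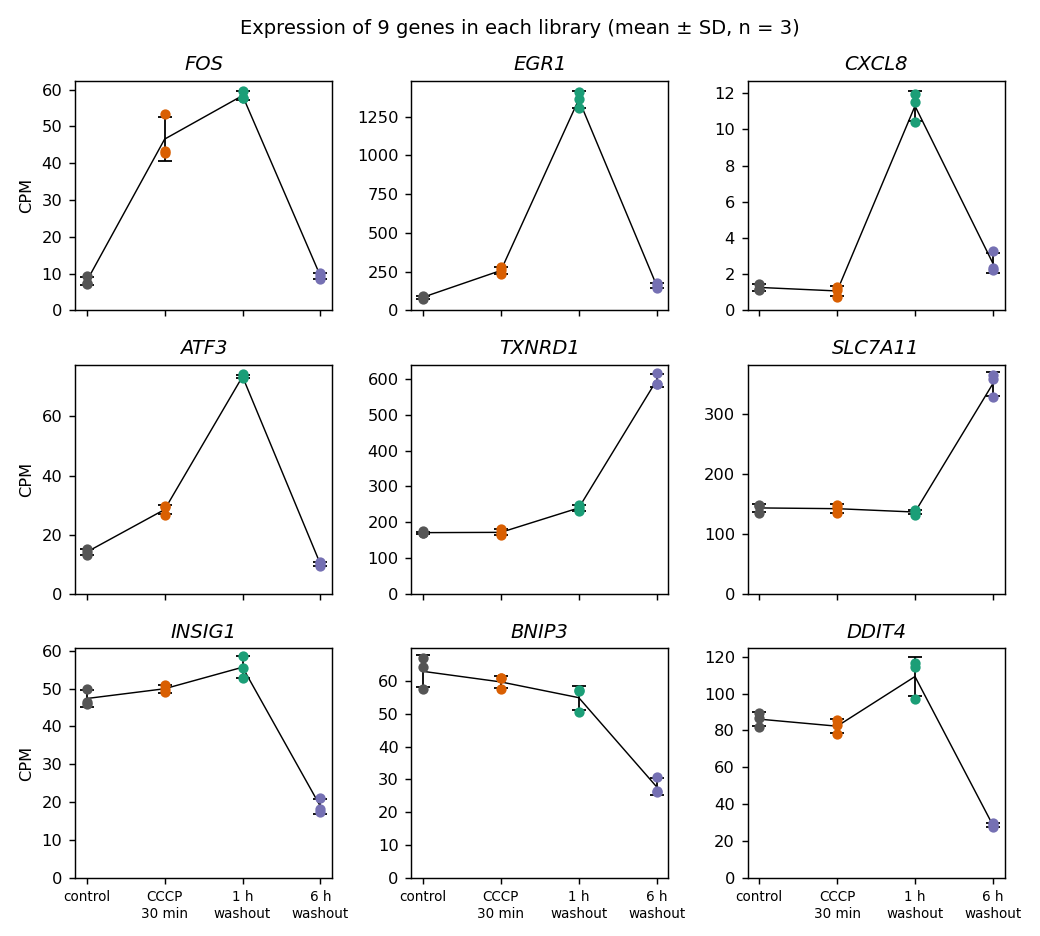
CPM (vertical axes) of 9 genes in each library of the 4 groups (horizontal axes), as points with the mean and SD of the 3 libraries per group. FOS is at 7.98 ± 1.18, 46.5 ± 5.96, 58.3 ± 1.14 and 9.34 ± 0.740 CPM in the 4 groups in order of time, and TXNRD1 at 171 ± 3.03, 172 ± 8.33, 240.0 ± 8.17 and 596 ± 18.1 CPM.

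Single genes outside these groups also changed at 6 h. Among genes with a symbol and a mean log2 CPM of at least 2, the largest rises were TRIM16L, which shares sequence with TRIM16, at 4.96-fold, RGS4, a regulator of G protein signalling, at 4.92-fold, the keratin-associated KRTAP2-3 at 4.59-fold and ESM1, a secreted proteoglycan, at 4.41-fold. RASSF6 (ENSG00000169435_14, chromosome 4, 73571550 to 73620631), a Ras association domain protein, fell 25.8-fold, from 12.5 ± 0.941 to 0.489 ± 0.183 CPM (edgeR adjusted p = 1.55e-17, n = 3 libraries per group). ABCG1, a cholesterol efflux transporter, fell 5.52-fold from 9.08 ± 0.115 to 1.63 ± 0.128 CPM, RGS16 4.94-fold and SOX2 4.68-fold. In total 6051 genes were called against control at 6 h, 3096 higher and 2955 lower, of which 222 rose and 549 fell at least 2-fold. Scaling to library size only called 2242 higher and 3828 lower (36.9% higher against 51.2%).

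Genes of the mitochondrion itself and of its clearance gave mixed results. The 13 protein-coding genes of mitochondrial DNA did not pass the preset camera test against control (adjusted p = 0.805, 0.641 and 0.448 at 30 min, 1 h and 6 h), with 1, 0 and 3 members fallen and 0 risen (1, 0 and 3 fallen and 1, 0 and 0 risen adjusted over the list alone). MT-CO1 was at 0.02 ± 0.05, -0.09 ± 0.05 and -0.17 ± 0.05 (adjusted p = 0.917, 0.238 and 0.00740) and MT-ND1 at -0.03 ± 0.10, -0.04 ± 0.10 and 0.06 ± 0.10 (adjusted p = 0.953, 0.862 and 0.728). At 1 h MT-CO1 passed with scaling to library size only (-0.15) and with the 2 groups fitted alone (-0.10). Nuclear oxidative phosphorylation genes did not pass it at 1 h or 6 h (adjusted p = 0.833 and 0.391), with 1 and 3 of 70 risen (0 and 1 adjusted over the list alone). The 19 mitophagy genes did not pass either (adjusted p = 0.0695, 0.154 and 0.757, and at 30 min as low as 0.0376 over 11 other settings, of which 2 passed), and at 6 h 4 of them rose and 3 fell (5 and 3 adjusted over the list alone). Among these, the autophagy receptor SQSTM1 was at 0.16 ± 0.05 (adjusted p = 0.241) at 30 min and rose by 0.61 ± 0.05 and 1.04 ± 0.05 at 1 h and 6 h, while the receptors BNIP3 and BNIP3L were at -1.18 ± 0.08 and -0.69 ± 0.05 at 6 h. PINK1, the kinase that marks depolarised mitochondria, was at 0.10 ± 0.09, 0.11 ± 0.09 and -0.17 ± 0.09 (adjusted p = 0.769, 0.513 and 0.166), and its 6 h value passed with scaling to library size only (-0.23) and after the GC correction (-0.20). For 18 genes of mitochondrial fusion and fission the adjusted p values were 0.997, 0.758 and 0.449, and at 6 h 4 rose and 2 fell (4 and 2 adjusted over the list alone). The coactivator PPARGC1A was at -0.08 ± 0.24, 0.09 ± 0.24 and -0.11 ± 0.24 (adjusted p = 0.941, 0.861 and 0.765).

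Among the genes fixed in advance, several did not pass at 30 min. DDIT3 was at -0.14 ± 0.13 (adjusted p = 0.762), GDF15 at 0.37 ± 0.17 (0.458), CHAC1 at 0.25 ± 0.09 (0.341), TRIB3 at 0.06 ± 0.10 (0.876) and HMOX1 at 0.05 ± 0.08 (0.881). TXNIP was at -0.36 ± 0.14 (0.381, and 0.0189 without the 3 libraries that deviated together), TFAM at -0.10 ± 0.06 (0.581), HSPD1 at 0.03 ± 0.05 (0.879) and ATF4 within 0.01 of 0 (SE 0.05, 0.996). At 1 h TFAM was at -0.01 ± 0.06 (0.929) and HSPD1 at 0.03 ± 0.05 (0.786), and at 6 h HMOX1 was at 0.46 ± 0.08 (1.58e-05). Lists that did not pass the preset camera test against control at any of the 3 times included the interferon-stimulated genes (adjusted p = 0.280, 0.070 and 0.234, and at 1 h as low as 0.0487 over 11 other settings, of which 1 passed; 3 of 18 fell and 1 rose at 6 h, 3 and 1 adjusted over the list alone). Another was that of S phase entry (0.211, 0.156 and 0.496; 5 of 25 rose and 3 fell at 6 h, 5 and 3 adjusted over the list alone). Markers of other cell types had 5 of 17 members tested and did not pass the preset camera test (0.650, 0.805 and 0.280; 2 fell at 6 h, 3 adjusted over the list alone).

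The fourth comparison followed the first hour after washout, 1 h against the end of the exposure. CXCL8 rose 10.6-fold from 1.07 ± 0.281 to 11.3 ± 0.811 CPM, FOSB rose by 2.97 ± 0.15, and ID1 and ID4, inhibitors of basic helix-loop-helix factors, rose 5.67-fold and 5.45-fold (edgeR adjusted p = 3.43e-24 and 3.01e-16, n = 3 libraries per group). EGR1 rose a further 5.29-fold, while FOS changed by 0.33 ± 0.08 (adjusted p = 0.0101, and 0.0706 and 0.0598 without CCCP replicate 2 or 1 h replicate 2). SOX2 fell 2.30-fold and SOCS3 2.12-fold. Of 31 immediate early genes 29 rose (29 adjusted over the list alone; camera adjusted p = 1.53e-278) and of 17 NF-kB targets 12 (14, 1.03e-56). The MAP kinase feedback list had 7 of 14 risen (11 risen and 1 fallen adjusted over the list alone, 1.05e-29), the YAP and TEAD list 8 of 20 (8 and 1, 2.30e-25), p53 targets 10 of 22 (10 and 1, 2.15e-11) and MondoA and FOXO targets 6 of 15, with 1 fallen (6 and 2, 2.08e-09). In the integrated stress response list 13 of 40 rose and 1 fell (14 and 1 adjusted over the list alone, 3.87e-10), its mean change was 0.20 and its median lay just below 0 while the test gave a rise. These 7 lists held with an estimated correlation. NRF2 targets rose in 4 of 21 cases (5 adjusted over the list alone; adjusted p = 0.00321, and adjusted p = 0.0577 with an estimated correlation). The mitotic, nuclear oxidative phosphorylation and ribosomal protein lists were lower, as 6 of 24, 1 of 70 and 1 of 71 fell (14, 0 and 1 adjusted over the list alone). Their adjusted p values were 3.90e-06, 0.00191 and 2.13e-05, and adjusted p = 0.140, 0.433 and 0.493 with an estimated correlation. Among the genes fixed in advance, ATF3 rose by 1.36 ± 0.07, DDIT3 by 1.29 ± 0.12, TXNIP by 1.08 ± 0.13, GDF15 by 1.00 ± 0.15, CHAC1 by 0.83 ± 0.09, HMOX1 by 0.59 ± 0.07, SQSTM1 by 0.44 ± 0.05 and ATF4 by 0.22 ± 0.05. TRIB3, PPARGC1A, TFAM, HSPA1A, PINK1, HSPD1, MT-ND1 and MT-CO1 did not pass, with log2 changes from -0.11 to 0.17 and adjusted p values from 0.190 to 0.980, and MT-CO1 passed without the 3 libraries that deviated together (-0.15). In this step 1152 genes were called, 813 higher and 339 lower, with 709 called without 1 h replicate 1 and 1801 after the GC correction. The share higher, 70.6%, was 59.5% with scaling to library size only (657 higher, 448 lower) and 59.7% after the GC correction (1076 and 725).

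The fifth comparison followed the later recovery, 6 h against 1 h. Immediate early genes came down and the NRF2, sterol and hypoxia groups moved in the direction they had at 6 h against control. EGR1 fell 8.48-fold, from 1362 ± 52.1 to 161 ± 15.1 CPM, FOS 6.23-fold, ATF3 7.22-fold, FOSB 18.8-fold and RASSF6 15.4-fold (edgeR adjusted p = 8.00e-14 for EGR1 and 6.76e-15 for RASSF6, n = 3 libraries per group). TRIM16L rose 4.19-fold, the divergent transcript APCDD1L-DT 3.99-fold and ESM1 3.26-fold. Of 31 immediate early genes 29 fell (29 adjusted over the list alone; camera adjusted p = 6.77e-114), of 22 cholesterol synthesis genes 20 (20, 2.89e-37), of 23 HIF targets 18 (19, 3.57e-19), of 22 p53 targets 16 (17, 2.48e-18) and of 15 MondoA and FOXO targets 12, with 1 risen (12 and 1, 7.23e-17). Of 21 NRF2 targets 13 rose (16, with 1 fallen, adjusted over the list alone; adjusted p = 1.91e-20), SLC7A11 by 1.36 ± 0.05 and TXNRD1 by 1.31 ± 0.05, and of 17 mitochondrial biogenesis genes 11 rose (11, 1.08e-04). NF-kB targets fell in 9 and rose in 2 of 17 cases (10 and 2 adjusted over the list alone, 8.54e-08), and YAP and TEAD targets in 13 and 5 of 20 (13 and 5, 7.77e-06). These 9 lists held with an estimated correlation, and 6 others did not. Glycolysis had 10 of 22 fallen and 1 risen (adjusted p = 1.17e-07, and 0.0976 with an estimated correlation), MAP kinase feedback 7 and 4 of 14 (6.40e-04 and 0.134), the endoplasmic reticulum response 5 fallen of 22 (0.0330 and 0.0810) and RNAs without a poly-A tail 7 fallen of 13 (0.0170 and 0.199). Mitochondrial chaperones had 5 of 15 risen (0.0362 and 0.0885) and ribosomal proteins 1 of 71 (0.0363 and 0.767), and adjusted over the list alone the members that passed in these 6 lists were 10 fallen and 1 risen, 7 and 4, 5 and 0, 9 and 0, 1 and 6, and 0 and 0. The preset adjusted p of the endoplasmic reticulum list was 0.0620 without 6 h replicate 1 and 0.0543 with the filter of at least 1 CPM in 3 libraries. That of the chaperone list was 0.060 and 0.0552 without 6 h replicate 2 or 3. That of the ribosomal list was 0.152, 0.166 and 0.227 without 1 h replicate 1 or 6 h replicate 2 or 3 and 0.241 without the 3 libraries that deviated together.

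Genes fixed in advance took several courses between 1 h and 6 h. SQSTM1 rose by 0.43 ± 0.05, TFAM by 0.32 ± 0.06 and HSPD1 by 0.30 ± 0.05, while GDF15 was at -1.95 ± 0.17, DDIT3 at -1.39 ± 0.12 and CHAC1 at -1.13 ± 0.09 (edgeR adjusted p from 1.51e-11 to 7.06e-05 over these 6 genes, n = 3 libraries per group). TRIB3 was at 0.31 ± 0.09 (adjusted p = 0.0159, and 0.0502, 0.0714, 0.0658 and 0.0742 without 1 h replicate 1 or 2 or 6 h replicate 1 or 2). PINK1 was at -0.28 ± 0.09 (adjusted p = 0.0249, and 0.0765, 0.0925, 0.0541 and 0.128 without 1 h replicate 1 or 3 or 6 h replicate 1 or 3, and 0.0545 without the 3 libraries that deviated together). HMOX1 was at -0.18 ± 0.07 (adjusted p = 0.0651, and 0.0402 and 0.0342 without 1 h replicate 2 or 6 h replicate 3 and 0.0153 without the 3 libraries). ATF4, HSPA1A, TXNIP, PPARGC1A, MT-CO1 and MT-ND1 did not pass, with log2 changes from -0.20 to 0.09, and MT-ND1 passed without the 3 libraries that deviated together (0.16). In this step 4945 genes were called, 2359 higher and 2586 lower, of which 178 rose and 353 fell at least 2-fold.

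**Figure D4:**
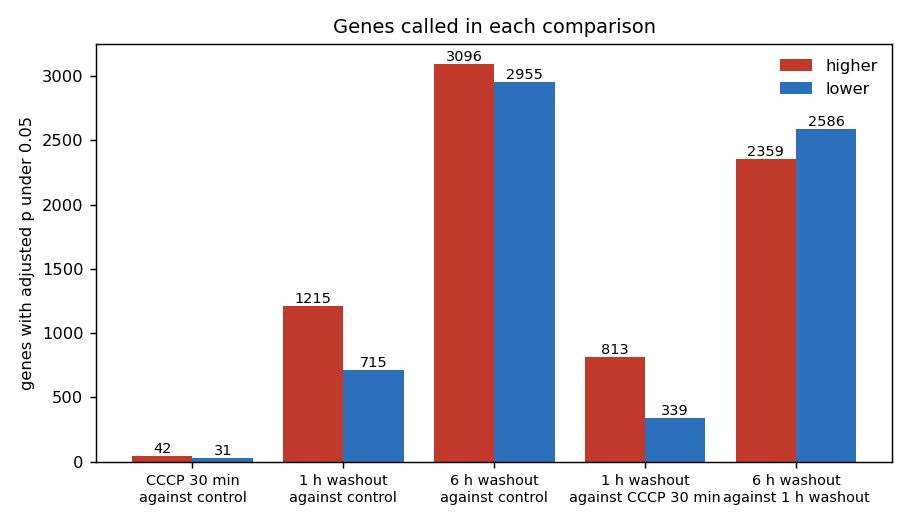
Number of genes called by edgeR (vertical axis, genes) in each of the 5 comparisons (horizontal axis), with the genes higher and lower in the first named group as separate bars. The 30 min comparison has 42 higher and 31 lower genes, and the comparison of 6 h with control has 3096 and 2955.

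The changes at the 3 times overlapped. Of the 73 genes called at 30 min, 46 were called in the same direction at 1 h (35 higher, 11 lower, against 2.72 and 1.18 for independent lists) and 45 at 6 h (30 and 15, against 6.92 and 4.88), while 4 were called in the opposite direction at 1 h and 9 at 6 h. At 1 h and 6 h 1139 genes were called in the same direction (739 higher, 400 lower, against 200.2 and 112 for independent lists), 77 were higher at 1 h and lower at 6 h, and 17 were lower and then higher. Because the 3 comparisons share their control libraries, unchanged groups and shared controls were simulated from the control means, with genes drawn independently. Over 20 draws they gave a mean of 0.1, 0.3 and 0.25 genes called in the same direction for the 3 pairs. Unchanged groups yield few calls in any comparison, so these means are low in advance and are no reference for lists of the real size. The 3 controls were too few to give each comparison its own pair, so part of the excess over independent lists may come from the shared controls. The log2 fold changes correlated across genes with Pearson r = 0.46, 0.28 and 0.49 for 30 min with 1 h, 30 min with 6 h and 1 h with 6 h, while simulated shared controls gave a mean r of 0.50, 0.50 and 0.49. Their covariances were 0.0469, 0.0367 and 0.0866 against simulated means of 0.0219, 0.0225 and 0.0217. The simulation held no GC effect, while the real changes against control had a Spearman rho with GC content of 0.38, 0.36 and 0.05 at 30 min, 1 h and 6 h. The simulated covariances may therefore be too low, and the excess does not by itself show a shared response. A single test for any difference among the 4 groups called 6971 genes, 37.1% of those tested. Without CCCP replicate 1 the 46 and 45 shared genes became 199 and 147, without CCCP replicate 3 they became 20 and 16, without control replicate 1 they became 26 and 22, without control replicate 2 they became 26 and 23, and without CCCP replicate 2 they became 29 and 26. The 46 became 29 and 27 without 1 h replicate 1 or 3, the 45 became 28 without 6 h replicate 2, and the 1139 became 723 without control replicate 1 and 717 without 1 h replicate 1.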

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

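In this part the test of fresh medium, the test of host transcripts, the bootstrap interval and the use of matched draws for ZNF genes, the GC correction and the fit without 3 libraries were chosen only after the result was seen. A set of 77 genes was called higher than control 1 h after washout and lower than control at 6 h, and 17 genes were called lower and then higher. All of them also had the difference between 6 h and 1 h called. Calls on opposite sides of control nearly fix that outcome in advance, so it is no further support. Examples chosen after their values were seen were ATF3 (2.37 ± 0.08 at 1 h and -0.48 ± 0.10 at 6 h, log2 ± SE), the mTORC1 inhibitor DDIT4 (0.34 ± 0.06 and -1.59 ± 0.07) and the cell cycle inhibitor CDKN1A (0.72 ± 0.06 and -0.51 ± 0.06), while L3HYPDH took the other course (-0.40 ± 0.10 and 0.90 ± 0.09). The 77 held 5 of 22 tested p53 targets, 4 of 22 cholesterol synthesis genes, 4 of 31 immediate early genes and at most 3 of any other list, and the 17 held 2 of 24 mitotic genes. These counts were not tested, since the genes were selected for their calls and some are in more than 1 list.

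The first pattern was the rise of immediate early and NF-kB genes 1 h after washout and the fall of sterol and hypoxia genes at 6 h. GC content was argued against, since after the GC correction the number of called members of each of the 4 lists was at least 100% of that without it. The rise of immediate early genes at 30 min came before the washout, but the labels do not say whether medium was changed when CCCP was added. For the changes after washout, recovery from CCCP and the change of medium cannot be told apart, because 0 libraries came from cells given fresh medium without CCCP. A candidate explanation for part of the rise at 1 h and of the fall at 6 h is therefore the serum, sterols or glucose of the new medium, and a control given fresh medium for 1 h and 6 h would test it.

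The second pattern was that more genes were detected in controls (31104 to 31326) than in treated libraries (29552 to 30619), and the median log2 change of long noncoding RNA genes lay below 0 at all 3 times, with no set test run on that class. Depth was argued against, since after thinning every library to 13512353 counts the lowest control lay 126 genes above the highest treated library. For GC content, 2632 genes under 1 CPM kept medians of -0.14, -0.23 and -0.24 at 30 min, 1 h and 6 h after the GC correction. That correction was fitted on genes with a mean log2 CPM above 2 and extended to these. A GC effect like that of abundant genes was thus argued against, and one particular to low-count genes stayed open. For genomic DNA in the controls, olfactory receptor genes had 26.3 CPM (over total counts, without TMM scaling) in controls and 21.9 in treated libraries. The ratio was 1.198 (95% interval 1.12 to 1.28, counting error only). It narrowly met the rule set beforehand against genomic DNA, a ratio under 1.2 with a looser bound on the interval. A stricter reading left the question open, since the interval reached past 1.2. A loss of short-lived RNA at 30 min stayed open. After the GC correction 444 ZNF genes had a median of -0.0340 (95% bootstrap interval over genes -0.0480 to -0.0178). This lay above the bound of -0.05 set beforehand to exclude such a loss, yet below 100% of expression-matched draws, so that bound was wrong in passing over a smaller fall. The median of 48 noncoding hosts of small RNA was -0.0832, below 99.6% of their draws. Without the GC correction the hosts' median was -0.08, and that of all tested long noncoding genes was -0.09. The draws were matched on expression and not on gene class, so the hosts cannot tell a short life from a fall of noncoding RNA in general. At 1 h and 6 h the ZNF median was below 4.7 and 19% of draws and that of the hosts below 51.3 and 0.2%. Values for RNAs without a poly-A tail and for unnamed loci moved too, and they cannot tell library selection from a change in the cells. Among 13 RNAs without a poly-A tail 0, 3 and 7 fell and 0, 1 and 0 rose at the 3 times (median log2 changes -0.02, -0.10 and -0.45, adjusted p = 0.705, 0.149 and 8.78e-04). Loci without a gene name took 0.327 to 0.335% of counts in controls and 0.250 to 0.270% at 6 h. A difference in poly-A selection and a lower yield of noncoding RNA in stressed cells may each account for part of the pattern, and no group tests either.

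The third pattern was the small rise of the ribosomal protein and nuclear oxidative phosphorylation lists at 30 min. After the GC correction their medians were 0.0944 and 0.0724. Without the correction they were 0.102 and 0.0794, and both of these lay above 100% of 1000 length-matched draws. Without each CCCP library in turn the lower of the medians was 0.0729 or more. These values argue against GC content, the gene length in the file and a single CCCP library as the whole cause. The members had median gene lengths of 3461 and 2661.5 bases in the file. The length of the expressed transcripts was not tested, so an effect of it stayed open. The adjusted p values of 0.196 and 0.265 with an estimated correlation leave open a shift that the members share by chance. A rise of these abundant transcripts in CCCP may be biological, and as a hypothesis it would need more libraries.

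Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05 in any single comparison. In the 30 min comparison the real split called 73 genes and 2 of the 10 splits called as many, since the split with control replicates 1 and 2 and CCCP replicate 1 on one side called 174, which points to a structure of these samples that their groups do not follow. The real split called 1930 genes at 1 h, 6051 at 6 h, 1152 for 1 h against the exposure and 4945 for 6 h against 1 h, and the highest of the other splits called 0, 0, 2 and 0, so the real one was the 1 split with as many in each. For any difference among the 4 groups, 1 of 100 splits, the real one, reached 6971 genes and the highest other reached 3637. That share is under 0.05 and argues against a chance division of the libraries there, though the splits were only a sample of those possible.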

How the results depend on the processing

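The GC correction and the fit without the 3 libraries that deviated together (control replicate 1, CCCP replicate 1 and 6 h replicate 3) were chosen only after the result was seen. Of 473 named pairs of gene and comparison, 431 were past the threshold, and over their 6032 values under an alternative 5576 stayed past it in the same direction, 456 did not and 0 were past it in the opposite direction. For 332 of these 431, no alternative run on the named pairs moved the call. Limma-voom, the fit without a low-count filter and the stricter adjusted p threshold were not applied to these pairs, so their effect on them stayed open.

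The 73 genes at 30 min became 161 without a low-count filter, 144 with the GC correction, 253 without the 3 libraries, 41 with the 2 groups alone, 38 with limma-voom and 28 at an adjusted p under 0.01, where the stricter threshold itself lowers the count and the other causes were not tested. The 1930 genes at 1 h became 3159 with the 2 groups alone and 936 at 0.01, the 1152 of the first recovery step 1801 with the GC correction and 628 at 0.01, and the 4945 of the second step 3250 at 0.01, and the cause was not tested except for the threshold. Lists called fell with an estimated correlation from 9 to 4 at 30 min, from 17 to 9 at 6 h, from 11 to 7 for the first step and from 15 to 9 for the second, and the cause was not tested. At 1 h the number went from 13 to 9. Genes called in the same direction at 30 min and 1 h went from 46 to 74 with the GC correction, 149 without the 3 libraries and 22 at 0.01, those at 30 min and 6 h from 45 to 72, 117 and 17 in the same order, and those at 1 h and 6 h from 1139 to 558 at 0.01.

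With 1 library left out, a group keeps 2 libraries and the fit pools the spread over groups. The counts then ran from 27 (without CCCP replicate 3) to 319 (without CCCP replicate 1) at 30 min, with 32, 33 and 46 without control replicate 1, control replicate 2 and CCCP replicate 2. They ran from 1134 to 1677 at 1 h, with 1190 and 1281 without control replicate 1 or 2 and 1134, 1246 and 1252 without 1 h replicate 1, 2 or 3. For the first recovery step they ran from 709 (without 1 h replicate 1) to 998. Shared genes ran from 20 to 199 for 30 min with 1 h, from 16 to 147 for 30 min with 6 h (lowest without CCCP replicate 3 and highest without CCCP replicate 1 in both) and from 717 (without 1 h replicate 1) to 1349 for 1 h with 6 h, and 723 without control replicate 1. The counts at 6 h (5004 to 5627), in the second step (3861 to 4510) and for any difference (5954 to 7802) stayed within 1.5 times.

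Libraries with the same replicate number did not deviate together (correlations of -0.32 to 0.32 over 18 pairs, and -0.37 to 0.51 over 36 pairs with other numbers, across 12495 genes), so no pairing by number was seen. A weaker pairing could be hidden by the shared deviation of the 3 libraries, and the labels do not say what a number marks. The replicate number as a block gave 52 genes at 30 min, 1820 at 1 h, 5934 at 6 h, 1090 and 4849 in the 2 steps and 6785 for any difference, 9, 13, 17, 11 and 15 lists, and 36, 31 and 1068 shared genes, all within 1.5 times of the values without it. Depth was varied only for the number of genes detected and not for the calls, so how far it limits calls stayed open. In a simulated comparison of 1 h with control over 18373 genes, 30% of genes with the smallest simulated change were recovered.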

Other observations

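In this part the loci without a gene name and the gene classes were singled out after their values were seen. By annotated class, 2774 tested long noncoding RNA genes had a median log2 change against control of -0.09 at 30 min, -0.17 at 1 h and -0.18 at 6 h, and 62.5, 67.8 and 66.2% of them lay below 0. The 13861 protein-coding genes had medians of 0.01, 0.02 and 0.01, and at 6 h edgeR called 160 long noncoding genes higher and 394 lower, against 2842 and 2285 protein-coding genes. At 30 min it called 0 long noncoding genes higher and 7 lower, and at 1 h 49 and 153. No set test was run on these classes. Of the 1215 genes called higher at 1 h, 739 were also called higher at 6 h, and 223 of those rose further between 1 h and 6 h while 99 came down. At 6 h 2340 genes were called higher that had not been called at 1 h.

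Among 4 tested genes of the metallothionein and zinc list, too few for a list test, MT2A, a metallothionein that binds zinc and copper, rose by 0.34 ± 0.06 at 30 min, 0.33 ± 0.06 at 1 h and 0.56 ± 0.06 at 6 h (log2 ± SE, edgeR adjusted p = 0.00105, 1.15e-04 and 4.84e-09, n = 3 libraries per group). Its 30 min change was 0.31 with an adjusted p of 0.108 after the GC correction and 0.31 with 0.145 without the 3 libraries that deviated together. SLC30A1, a zinc exporter, rose by 0.56 ± 0.06 at 1 h and was at -0.21 ± 0.06 at 6 h (adjusted p = 3.27e-08 and 0.00873), and its 6 h value was -0.17 with an adjusted p of 0.0615 without control replicate 1, -0.18 with 0.0529 after the GC correction and -0.15 with 0.0676 without the 3 libraries. In the list, 1, 2 and 1 of the 4 rose at the 3 times and 0, 0 and 1 fell (1, 2 and 2 rose and 0, 0 and 1 fell adjusted over the list alone).

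Of 232 tested loci that the deposited table lists without a gene name, 23 were called higher and 74 lower at 6 h. A locus on chromosome 2 (75239210 to 75279761, plus strand), 39690 bases from TACR1, the gene of the substance P receptor, was at 1.82 ± 0.398 CPM in controls, 2.20 ± 0.258 at 30 min, 2.68 ± 0.525 at 1 h and 32.8 ± 0.938 CPM at 6 h, a log2 change of 4.16 ± 0.15 (edgeR adjusted p = 1.17e-19, n = 3 libraries per group). Another on chromosome 18 (59705755 to 59715678, minus strand), 8093 bases from CCBE1, went from 15.3 ± 0.617 in controls to 3.39 ± 0.911 CPM at 6 h (log2 change -2.17 ± 0.15, adjusted p = 8.41e-13). Both were chosen after their values were seen.

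The deposited comparisons of the authors called 52 genes at 30 min at an adjusted p under 0.05, 1907 at 1 h, 4424 at 6 h, 792 for the first recovery step and 3872 for the second. Of these, 42, 1467, 4372, 746 and 3778 were also called by edgeR here, each in the same direction.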
